A study of Mus musculus with 36 samples.

How the data were processed

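Hippocampus RNA was sequenced from 36 adult mice, 3 males and 3 females of each of 6 inbred strains (129S1/SvImJ, A/J, C57BL/6J, DBA/1J, DBA/2J and PWD/Ph), on an Illumina HiSeq instrument. Per the labels' protocols, each library comes from the whole hippocampus of 1 animal aged 62 to 64 days, the replicates are separate animals, PWD/Ph mice were housed singly and the other strains in groups. The spike-in RNA mix differed between males and females, and no spike-in value was used here. Libraries shared sequencing lanes, but which libraries shared a lane is not given in the sources used here.

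The deposited data are 1 table per strain, with a column of counts and a column of FPKM per library, per the file headers. The counts are whole numbers per Ensembl gene that the authors had not scaled between libraries. The FPKM values are the authors' fragments per kilobase of transcript, scaled to each library's mapped fragments, and whether the authors also scaled them between libraries is not stated. Per the submitters' processing notes, the tools include Trimmomatic 0.32, TopHat2 2.0.13, SAMtools, DESeq2 1.8.1 and Cufflinks 2.1.1, with the build GRCm38 (mm10). The read counter, the strand setting and the annotation release behind the counts are not given in the sources used here. Antisense genes, overlapping genes and copies of multi-copy families are therefore reported as uncertain.

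Each table holds 37315 Ensembl genes, of which 35449 were matched to a symbol by their identifier and 1866 were not. Coordinates are those of the GENCODE M21 annotation of GRCm38, 1-based. Total counts ran from 6493512 in DBA/2J female replicate 3 to 35232515 in PWD/Ph male replicate 3, with a median of 21144604. A filter on low counts (edgeR's filterByExpr over the 12 groups, minimum count 10, minimum total 15) kept 19702 genes, 52.8% of the table. Levels are CPM (counts scaled to a common library size) computed from the counts with the scaling below, and are given as mean ± SD over the libraries of a group or strain.

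All 36 libraries entered 1 model with a mean for each of the 12 groups. Counts were scaled by the trimmed mean of M values (TMM) and tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 24 residual degrees of freedom and a common dispersion of 0.0132, a coefficient of variation of 11.5% between replicates. The comparisons were female minus male averaged over the 6 strains, female minus male within each strain, the interaction of sex and strain (an F test of the 5 differences between the within-strain effects), each strain minus the mean of the other 5, and DBA/2J minus DBA/1J. Log2 fold changes carry an approximate standard error (SE), the absolute log2 fold change divided by the square root of its F statistic. It is least reliable for genes with very few counts in a group. The 6 strain comparisons are not independent, since they sum to 0.

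Before the data were examined, the tests, the samples in each, the alternatives, 35 lists of genes (cell type markers, functional groups and disease genes) and the rule for naming genes had been fixed. The rule took genes past the threshold with a mean of at least 1 CPM. For the averaged sex effect it took up to 12 genes per direction with the smallest p among those with the same sign in all 6 strains. Within a strain it took up to 8 per direction with the largest change among genes whose 3 female and 3 male libraries did not overlap, leaving out Xist and Y-linked genes. For the interaction it took the 10 genes with the smallest p. For strains it took up to 5 per direction with the largest change among genes whose libraries did not overlap those of the other strains. From each gene list described it took 2 to 4 members with the smallest p, and it took every gene of a list of strain variants known to alter RNA, and 5 sex-linked genes as a check of the labels. Genes outside the rule are marked as such. Some genes that the rule names are not reported here. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The camera test compares a list with all other genes, and fry asks only whether a list's members move on balance one way. Adjustment ran over the 35 lists of the averaged sex effect, over the 210 tests within strains and over the 245 tests between strains.

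The alternatives fixed in advance were DESeq2's size factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2's own test, the replicate number as a block, each strain's own 6 libraries, limma on log2 of the deposited FPKM plus 0.1 or 1, leaving out each strain, and leaving out each library. Chosen only after the data had been seen were a correction of each library's loess trend (span 0.5) on GC content and log transcript length, covariates from marker genes, thinning of counts to the shallowest library, leaving out libraries that stood apart, and leaving out each library for the gene lists. GC content was available for 19147 of the 19702 tested genes (97.2%). Other splits of the libraries were also refitted, up to 40 for each comparison. The 12 genes with a blank FPKM entered no FPKM test.

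The fits were tested on simulated data with 200 changed genes. Each gene was drawn independently around a mean shared by all libraries. The simulation thus held no strain differences and, except where stated, no library-wide trends, so recovery in the real data may differ. For the averaged sex effect (19177 simulated genes past the filter) 79.0% of the genes changed 1.5-fold and 96.0% of those changed 2-fold were called. For the sex effect in A/J (19191 genes) these shares were 53.0% and 74.0%, in DBA/2J (19192 genes) 34.0% and 69.0%, for the interaction (19191 genes) 26.0% and 51.0%, for A/J against the other strains (19171 genes) 75.0% and 91.0%, and for the DBA comparison (19164 genes) 54.0% and 79.0%. A simulated GC trend in A/J females (18643 genes) led to 1078 calls among unchanged genes, and to 13 after the correction. That trend was linear in GC content, a form the correction is built to remove.

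The precision of low levels is set by depth. A level of 0 over a group was compared through a floor of 3 counts over that group, giving a bound, and for totals of 1 to 3 counts the ratio is given with its exact 95% interval. Floors and intervals cover counting error only, and not reads that fail to align where a strain's sequence differs from the GRCm38 build. For 3 libraries against 3, the smallest exact two-sided p is 0.1, so single genes within a strain rest on the model's shared estimate of the spread. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Biostrings 2.70.1, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.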

Results

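The data describe gene expression in the hippocampus of adult male and female mice of 6 inbred strains, and allow the sexes to be compared within each strain and the strains with each other. Each of the 12 groups of strain and sex had 3 libraries. Females were 1 day older than males in 129S1/SvImJ, A/J and DBA/1J (63 against 62 days) and in C57BL/6J (64 against 63), and both sexes were 62 days old in DBA/2J and PWD/Ph. In the former 4 strains sex and age therefore cannot be told apart, which extends to the average over strains and to the interaction test. Total counts per library ran from 18695669 to 27591550 in 129S1/SvImJ, from 20923565 to 28675309 in A/J, from 14283060 to 23880351 in C57BL/6J and from 16348030 to 26699617 in DBA/1J. In DBA/2J they ran from 6493512 to 21607811, with 3 shallow libraries (7814418 in male replicate 2, 7422602 in female replicate 2 and 6493512 in female replicate 3). PWD/Ph libraries had 10551361 to 35232515.

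Strain set the libraries apart more than sex did. The first 2 principal components of the log2 CPM held 30.8% and 15.8% of the variance. Across the tested genes, which are not independent replicates, the median correlation between libraries was 0.9882 within a group, 0.9850 between the sexes of a strain and 0.9566 between strains.

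**Figure D1:**
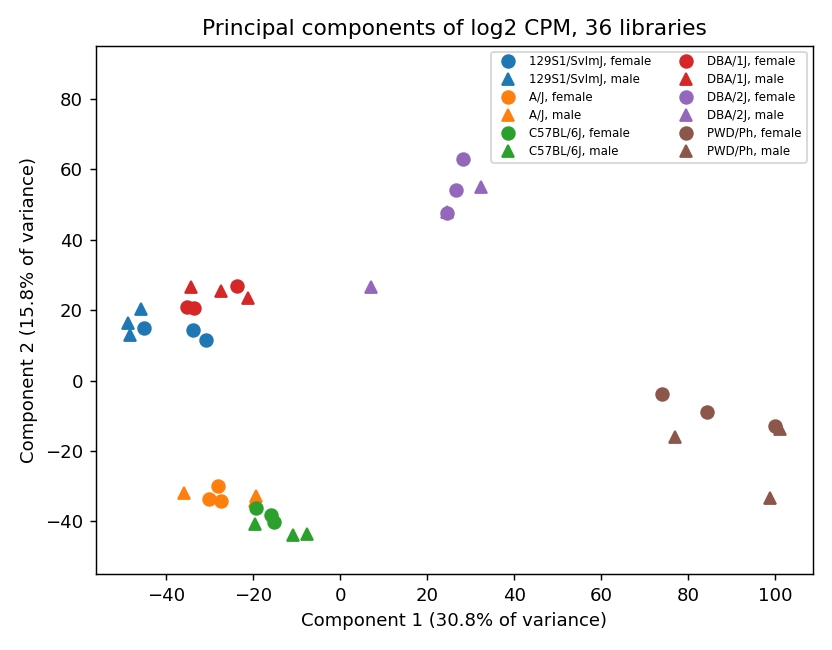
Principal component 1 (x axis, 30.8% of the variance) against component 2 (y axis, 15.8%) of log2 CPM, 1 point per library, colour for strain and marker for sex. Libraries grouped by strain rather than by sex, and DBA/2J male replicate 1 lay apart from the other DBA/2J libraries.

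The sex labels matched the sex-linked genes in all 36 libraries. Xist, the RNA that coats the inactive X chromosome, had 6738 to 25592 counts in the 18 females (814 CPM ± 178, SD) and 19 to 209 in the 18 males (3.53 ± 3.09). The Y-linked gene Ddx3y had 543 to 2760 counts in males (56.8 CPM ± 17.6) and 0 to 1 in females. Eif2s3y stood at 37.7 CPM ± 9.67 in males and had 0 to 6 counts in females. Kdm5d had 176 to 899 counts in males against 0 to 2, and Uty 136 to 796 against 2 to 42.

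Averaged over the 6 strains, the clearest differences between the sexes outside the Y chromosome and Xist were X-linked genes higher in females. Eif2s3x, a subunit of a translation initiation factor (ENSMUSG00000035150, chromosome X, 94188707 to 94212862), was 1.61-fold higher in females (log2 0.69 ± 0.04, SE, 18 females and 18 males), and passed the test in each strain. Its levels ran from 149 CPM in females against 97.9 in males of DBA/1J to 249 against 177 in PWD/Ph. The histone demethylase Kdm6a (chromosome X, 18162575 to 18279936) was 1.41-fold higher, the RNA helicase Ddx3x (chromosome X, 13280970 to 13294052) 1.32-fold and the histone demethylase Kdm5c 1.20-fold. Among autosomal genes with the same sign in all 6 strains, Dbp, a clock-controlled transcription factor (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), was 1.34-fold higher in females (log2 0.42 ± 0.06).

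By edgeR 47 of 19702 genes passed, 22 higher in females and 25 higher in males, with 10 on the X chromosome, 4 on the Y chromosome and 29 on autosomes. The split was 59 higher and 116 lower in females by DESeq2's test, 51 and 113 without the low-count filter and 191 and 601 without 129S1/SvImJ. Of the 47 genes, 12 differed by over 1.5-fold, and 14 higher and 12 lower genes had the same sign in all 6 strains. edgeR's adjusted p was 3.03e-15 for Eif2s3x, 6.29e-10 for Kdm6a, 1.35e-06 for Ddx3x, 0.000141 for Kdm5c and 0.00034 for Dbp. Also higher in females were Pbdc1 (chromosome X, log2 0.18 ± 0.04), Fam155a (0.13 ± 0.03), Ankrd63 (0.24 ± 0.05), the X-linked transcript 5530601H04Rik (0.34 ± 0.05) and the pseudogene Gm2223 (0.68 ± 0.07), whose reads its source gene could share. Tsix (5.11 ± 0.15) lies antisense to Xist, and the counts may not separate the strands. Higher in males beside the 4 Y-linked genes were Plod1, a collagen lysyl hydroxylase (-0.22 ± 0.05), Gramd3 (-0.23 ± 0.05), Fam114a2 (-0.16 ± 0.04), the non-coding Gm13166 (-0.52 ± 0.10), the pseudogene Gm15645 (-0.29 ± 0.06) and ENSMUSG00000074140 (-0.32 ± 0.06). The calls of Fam155a, Pbdc1, Ankrd63, Gm13166, Gramd3, Plod1, Fam114a2 and Gm15645 each ended without some single library, with edgeR's adjusted p reaching 0.0941 for Ankrd63 without 129S1/SvImJ female replicate 3. The libraries whose absence ended the calls of 7 or 8 of the 22 named genes were C57BL/6J female replicates 1 and 2, DBA/1J female replicate 1, DBA/2J male replicate 1 and PWD/Ph male replicate 3. The total reached 167 without 129S1/SvImJ male replicate 3, 82 without female replicate 2 of that strain, and 95 and 77 without PWD/Ph female replicates 2 and 3. It fell to between 18 and 31 without 129S1/SvImJ female replicate 3, A/J males 1 and 2 or females 1, 2 and 3, C57BL/6J males 1 and 2 or females 1 and 2, DBA/1J female replicate 1, DBA/2J male 1 or females 1 and 3, or PWD/Ph male 3 or female 1.

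Among the gene lists, X genes reported to escape inactivation were higher in females on average, with 6 of 13 measured members past the threshold over all genes and 7 when adjusted over the list alone, none lower (camera adjusted p = 3.84e-19, and adjusted p = 1.27e-05 with an estimated correlation). The 4 measured Y-linked genes were all lower in females (adjusted p = 6.47e-24 with an estimated correlation). Of 4 RNAs of the X-inactivation centre 2 were higher (adjusted p = 3.6e-13 with an estimated correlation). Circadian clock genes were higher in females by camera (adjusted p = 0.00524, but adjusted p = 0.23 with an estimated correlation) and by fry (adjusted p = 0.00549). Of the 17 measured clock genes 1 passed over all genes, Dbp, and 4 higher and 1 lower passed when adjusted over the list alone. Ciart, a repressor of the clock, had log2 0.32 ± 0.08, Nr1d2 0.15 ± 0.04 and Arntl, the positive arm's core factor, -0.13 ± 0.04. Time of day at collection did not enter the model, so its part in the clock genes, Dbp included, was not tested. Mitochondrially encoded genes had a median log2 of 0.14 over 37 members, with 0 past edgeR's threshold over all genes or over the list alone (camera adjusted p = 2.83e-05, but adjusted p = 0.963 with an estimated correlation). GABA receptors (17 members, 0 past either threshold) and choroid plexus markers (22 members, 0 past either) gave camera adjusted p = 0.0364 and 0.0421, but adjusted p = 0.892 and 0.963 with an estimated correlation.

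The camera call of GABA receptors was lost, with an adjusted p up to 0.134, without any 1 of 129S1/SvImJ male 2 or female 3, A/J male 2, C57BL/6J male 3, DBA/1J male 2 or female 3, DBA/2J male 1 or female 3, and PWD/Ph male 2 or female 2. That of choroid plexus markers was lost, up to 0.551, without any 1 of 129S1/SvImJ male 3 or female 1, A/J male 2 or female 2, C57BL/6J male 3 or female 3, DBA/1J male 1 or female 3, DBA/2J males 1 and 2 or female 1, and PWD/Ph male 1 or females 2 and 3.

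**Figure D2:**
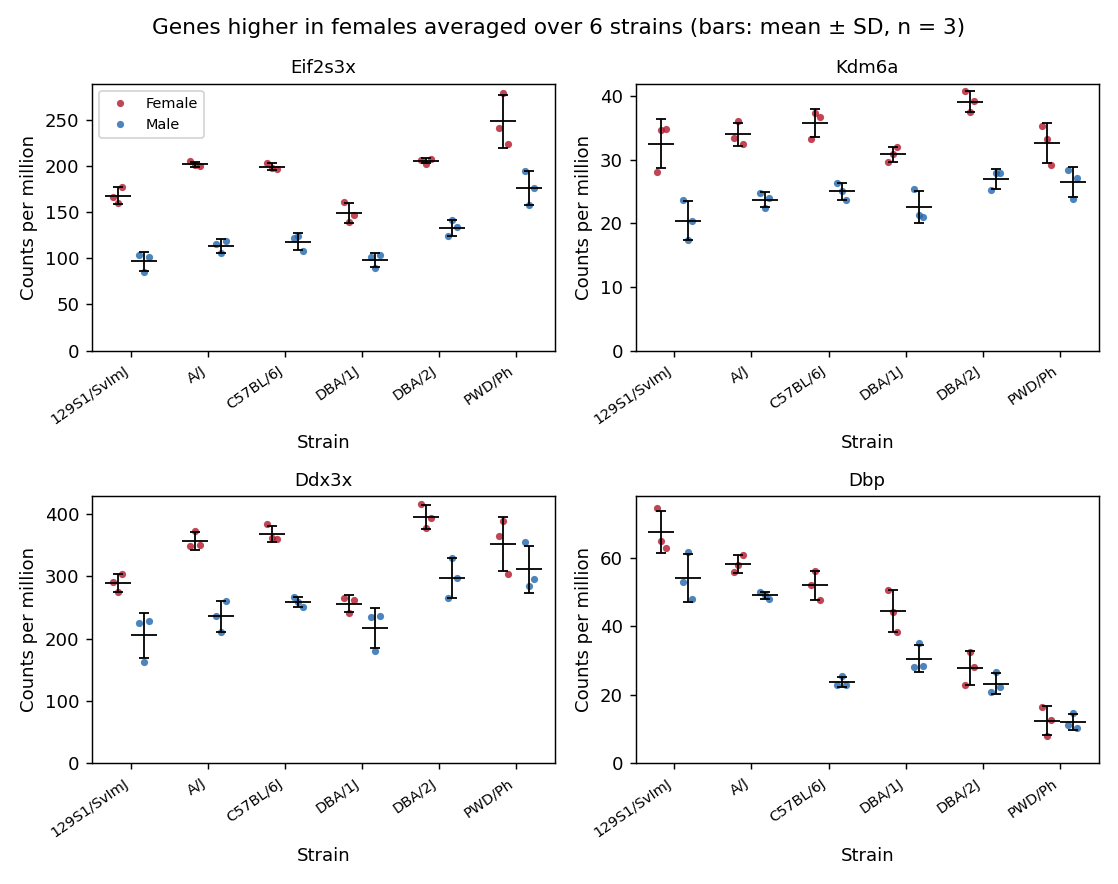
CPM (y axis) of Eif2s3x, Kdm6a, Ddx3x and Dbp in each library by strain and sex, with points for libraries and bars for mean ± SD (n = 3). Eif2s3x was higher in females of every strain, and Dbp differed most in C57BL/6J, with 52.0 CPM in females and 23.7 in males.

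Within single strains the number of genes that differed between the male and female groups ran from 10 in DBA/2J to 1049 in A/J, where the females were 1 day older. Genes named for the size of their sex effect within a strain had no overlap between their 3 female and 3 male libraries, an arrangement with an exact two-sided p of 0.1 for a single gene. Genes named from lists, from the interaction test or after their values were seen were not held to this.

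**Figure D3:**
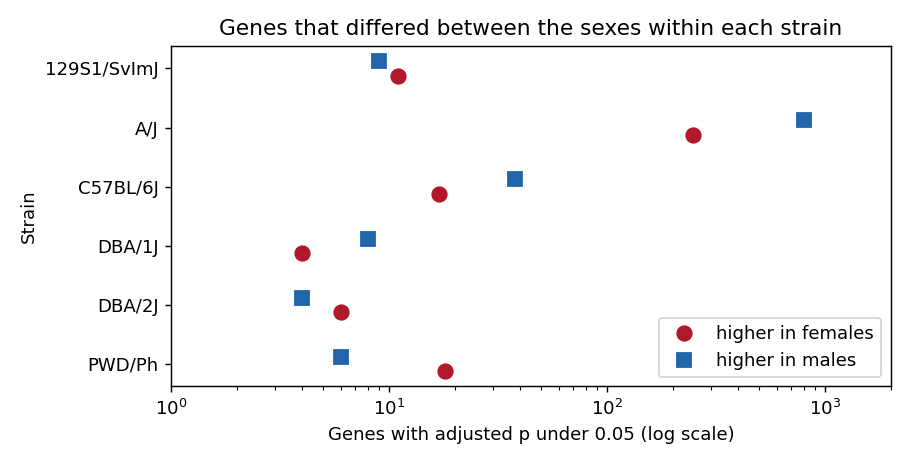
Number of genes past the threshold in each strain (log axis) that were higher in females and higher in males. A/J had 249 and 800, C57BL/6J 17 and 38, and DBA/2J 6 and 4.

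In 129S1/SvImJ, females had lower Cldn5, the main tight-junction protein of brain endothelium (20.9 against 41.6 CPM, log2 -0.998 ± 0.197, n = 3 per sex), and lower Mmp14, a membrane-bound matrix metalloproteinase (9.30 against 15.3 CPM, -0.72 ± 0.12). Atr, a kinase of the DNA damage response, was higher in females (11.01 against 6.36 CPM, 0.78 ± 0.14), as was Dpyd, which degrades pyrimidines (8.29 against 5.38 CPM, 0.62 ± 0.12). Also higher were Eif2s3x (0.79 ± 0.09), Kdm6a (0.67 ± 0.10), the pseudogenes Gm2223 (0.91 ± 0.17) and Ppp1r2-ps4 (0.71 ± 0.15) and ENSMUSG00000072894 (0.65 ± 0.14). Lower were Rflnb (-0.58 ± 0.12), Ier5 (-0.54 ± 0.11) and the small nuclear RNA Gm22513 (-1.79 ± 0.35). The edgeR test passed 20 genes, 11 higher and 9 lower in females, 10 of them autosomal. edgeR's adjusted p was 0.0257 for Cldn5, 0.00315 for Mmp14 and 0.012 for both Atr and Dpyd. By limma on the deposited FPKM plus 0.1 the split was 2 higher and 3 lower. Of 13 named calls, Tsix included, 10 ended without female replicate 2, Mmp14 (adjusted p = 0.0732) and Cldn5 (0.339) among them, and 8 genes passed in all. Without female replicate 3, 9 calls ended (9 genes left), and without male replicate 2, 8 (11 left). Without male replicate 1, 4 calls ended, and without male replicate 3, 3, where 41 genes passed. Without female replicate 1, 368 genes passed.

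Oligodendrocyte and myelin markers had a median log2 of -0.47 in 129S1/SvImJ females, with 0 of 19 past edgeR's threshold over all genes and 13 lower when adjusted over the list alone (camera adjusted p = 3.42e-14, but adjusted p = 0.196 with an estimated correlation; fry adjusted p = 0.0402). Among them Cnp, an enzyme of the myelin sheath, had log2 -0.58 ± 0.14 and Cldn11, the tight-junction protein of myelin, -0.55 ± 0.15. Of 18 endothelial and mural markers, 1 passed over all genes, Cldn5, and 5 lower when adjusted over the list alone (camera adjusted p = 8.14e-07, but adjusted p = 0.186 with an estimated correlation; fry adjusted p = 0.0266). Choroid plexus markers had a median log2 of -2.12 with 0 past either threshold (adjusted p = 2.52e-07, but adjusted p = 0.722 with an estimated correlation). The mean log2 CPM of that list was 2.63 ± 2.18 in males and 1.13 ± 1.10 in females. Meningeal fibroblast markers (0 of 16 over all genes, 6 lower over the list alone) gave adjusted p = 1.51e-06, but adjusted p = 0.458 with an estimated correlation. Col3a1, a fibrillar collagen, had log2 -1.79 ± 0.41. Camera also called ependymal and ciliated, erythrocyte, interferon and MHC class I, and immediate early genes lower, and GABA receptors, epilepsy genes and autism and intellectual disability genes higher. None of their members passed edgeR's test over all genes, and adjusted p was 0.271 to 0.855 with an estimated correlation. Each of these calls ended without 1 or more of male replicates 1 and 2 and females 1, 2 and 3 (up to 0.597). X genes reported to escape inactivation were higher (2 of 13 over all genes, 6 adjusted over the list alone; adjusted p = 0.00427 with an estimated correlation).

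In A/J, males had more than double the level of Dcaf1, a substrate receptor of a ubiquitin ligase, with 571 CPM against 236 in females (log2 -1.28 ± 0.11, n = 3 per sex; chromosome 9, 106821874 to 106880992). The transcription factor Rreb1 stood at 114 CPM in males against 56.6 in females (-1.01 ± 0.15), Trank1 at 273 against 171 (-0.67 ± 0.09), the transporter Abcc5 at 131 against 92.7 (-0.50 ± 0.08) and Snapc4, of the complex that transcribes small nuclear RNAs, at 35.9 against 21.9 (-0.71 ± 0.11). Females had more RNA of 6 immediate early genes, which follow neuronal activity. Fos (log2 1.52 ± 0.35), Dusp1 (1.00 ± 0.22), Btg2 (0.79 ± 0.21) and Dusp6 (0.36 ± 0.09) were among them. The mucins Muc3a (0.57 against 2.02 CPM, -1.79 ± 0.37) and Muc6 (2.66 against 9.15 CPM, -1.78 ± 0.42) were lower in females.

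In edgeR's test 1049 genes passed in A/J, 249 higher in females and 800 higher in males, of which 937 were autosomal and 594 differed by over 1.5-fold. edgeR's adjusted p was 5.59e-09 for Dcaf1, 0.000194 for Rreb1, 5.72e-05 for Trank1 and 0.00534 for Muc3a. Of the calls 23.7% were higher in females with TMM, and 222 were higher and 877 lower with DESeq2's size factors. The share was 40.1% of 1562 calls after the correction for GC content and length (23.4% of 995 over the same tested genes before it), and 60.4% of 1236 by limma on the deposited FPKM plus 0.1. Those 1236 held 747 genes higher and 489 lower in females, the opposite majority, and only 470 of them were among the 1049. Members of multi-copy families and antisense genes are uncertain, among them Gm10715 (log2 2.69 ± 0.61), Gm10722, Gm10721, Gm10719, Gm10717, Gm10800, Gm3883, Gm21093, Prkag2os1, Gm10855, Gm17907 and ENSMUSG00000095552 (-5.36 ± 1.09). ENSMUSG00000092872 (8.82 against 1.54 CPM, log2 2.52 ± 0.30) has a deposited FPKM of 0 in all libraries. Without male replicates 1 or 3 or female replicates 1, 2 or 3 the total fell to 204, 544, 218, 618 or 394. The calls of Muc3a and Muc6 ended without male 1 (adjusted p = 0.0632 for Muc3a) or female 1 (0.1 for Muc6). Of the 16 named calls, 12 ended without female 1, 7 without female 3, male 1 or male 3, and 5 without male 2.

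Of 22 immediate early genes, 6 were higher in A/J females over all genes and 12 when adjusted over the list alone, with a median log2 of 0.55 (camera adjusted p = 3.31e-09, but adjusted p = 0.221 with an estimated correlation; fry adjusted p = 0.0147). Of 37 mitochondrially encoded genes, 12 were higher over all genes and 28 over the list alone. The transfer RNAs mt-Ti (1.65 ± 0.35) and mt-Tl2 (2.09 ± 0.46) were among them. The median log2 was 0.62, and 0.37 after the correction for GC content and length (camera adjusted p = 1.2e-17, but adjusted p = 0.433 with an estimated correlation). Mitochondrial genes made up 8.21%, 6.61% and 8.46% of the counts in A/J males and 9.58%, 9.72% and 9.12% in females. Astrocyte markers (2 of 15 higher over all genes and over the list alone) gave adjusted p = 0.0278, but adjusted p = 0.626 with an estimated correlation, and lost the call without male 1 or female 3 (up to 0.299). Interneuron markers (0 of 22 past either threshold) gave adjusted p = 0.0114, but adjusted p = 0.458 with an estimated correlation. GABA receptors (1 of 17 higher) gave 0.0258, but adjusted p = 0.758 with an estimated correlation, and 0.0878 without male 2.

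In C57BL/6J, Dbp was more than double in females (52.0 against 23.7 CPM, log2 1.13 ± 0.15, n = 3 per sex), while Dcaf1 was again higher in males (501 against 288 CPM, -0.80 ± 0.11). Ide, the insulin-degrading enzyme, stood at 70.6 CPM in males against 39.3 in females (-0.85 ± 0.10). Lower in females were Slc13a1, a sulfate transporter (4.91 against 10.8 CPM, -1.14 ± 0.22), Dnah5, a dynein heavy chain of motile cilia (4.02 against 8.05 CPM, -1.003 ± 0.197), Coro6 (6.06 against 11.8 CPM, -0.96 ± 0.22), BC030499 (2.31 against 4.78 CPM, -1.05 ± 0.21) and the non-coding Gm16244 (-1.15 ± 0.23). The pituitary hormone genes Gh (log2 -6.72 ± 1.16) and Pomc (-2.37 ± 0.51) were also lower in females. Gh had 196, 769 and 11 counts in the 3 males and 0, 7 and 4 in the females, Pomc 34, 187 and 20 against 6, 31 and 22. Prl, chosen after its values were seen, had 56, 492 and 1 against 0, 8 and 3.

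By edgeR 55 genes passed in C57BL/6J, 17 higher and 38 lower in females, 42 of them autosomal. edgeR's adjusted p was 5.22e-05 for Dbp, 0.0147 for Slc13a1, BC030499 and Dnah5, 0.0344 for Gh and 0.0361 for Pomc. After the correction for GC content and length 38.2% of 136 calls were higher in females, against 26.4% of 53 before it over the same tested genes. Without the 2 males with over 100 Gh counts, chosen after the values were seen, 12 genes passed, but that fit sets 1 male against 3 females and takes the spread from the other groups. Ccdc74a (0.58 ± 0.13, adjusted p = 0.0476) lost its call without any 1 of the 6 libraries. Gh lost its call without any except male replicate 3 (up to 0.199), and Pomc without male replicate 2 (0.526) or any female. The call of Slc13a1 ended without males 1 or 2 or females 1 or 2 (up to 0.157), and that of BC030499 without male 2 or females 1 or 2 (up to 0.175). That of Dnah5 ended without male 1 or females 1 or 2 (up to 0.167), that of Gm16244 without male 3 or females 1 or 2 (up to 0.165), and that of Coro6 without any except female 3 (up to 0.342). Dbp and Eif2s3x (0.76 ± 0.09) kept theirs. The count was 25, 18, 17 and 16 without males 1 and 2 and females 1 and 2, and 90 without female 3. Uncertain calls of multi-copy or unplaced genes were Gm10722 (2.95 ± 0.66), Gm10715 (2.78 ± 0.62), ENSMUSG00000092872, ENSMUSG00000081535 and the pseudogene Gm10045. The difference between strains was not past the threshold for Gh (interaction adjusted p = 1 by edgeR) or Pomc (0.0953).

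Circadian clock genes were higher in C57BL/6J females, which were also 1 day older than the males, with 2 of 17 past edgeR's threshold, Dbp and Bhlhe41 (0.35 ± 0.08), a repressor of the clock, and 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.42e-05, but adjusted p = 0.0616 with an estimated correlation; fry adjusted p = 0.00518). Ciart had log2 0.73 ± 0.18, while Arntl moved the other way (-0.35 ± 0.10). Time of day at collection did not enter the model, so its part in these differences was not tested. Mitochondrially encoded genes had a median log2 of 0.51, with 0 of 37 past the threshold and 19 higher when adjusted over the list alone (camera adjusted p = 4.74e-17, but adjusted p = 0.456 with an estimated correlation). They took 10.1%, 10.8% and 10.2% of the counts in males and 12.9%, 11.9% and 11.4% in females. X genes reported to escape inactivation were higher (3 of 13 over all genes; 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation). Choroid plexus markers gave camera adjusted p = 0.00535, but adjusted p = 0.886 with an estimated correlation, and 0.531 without male replicate 3.

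In DBA/1J, Hsp90b1 and Calr, which encode chaperones of the endoplasmic reticulum, were lower in females. Hsp90b1 stood at 202.37 against 289.00 CPM (log2 -0.51 ± 0.10, n = 3 per sex) and Calr at 259 against 353 (-0.45 ± 0.09). The sterol synthesis enzyme Cyp51 stood at 35.2 against 45.9 CPM (-0.38 ± 0.08), and Bccip was lower by log2 -0.47 ± 0.09, while Eif2s3x was higher (0.61 ± 0.09). The edgeR test passed 12 genes, 4 higher and 8 lower in females, 5 of them autosomal. edgeR's adjusted p was 0.0345 for Hsp90b1, Calr and Bccip and 0.0491 for Cyp51. By limma on FPKM plus 0.1 the split was 1 higher and 4 lower. The calls of Hsp90b1 (adjusted p up to 0.748) and Calr (up to 0.697) were kept only without male replicate 2, which gave 69 genes. Cyp51 also kept its call without male replicate 1, and Bccip without males 1 and 2 and female 2, while 7 genes passed without male 3 or female 1. Immediate early genes had a median log2 of -0.21 with 0 of 22 past either threshold (camera adjusted p = 5.13e-05, but adjusted p = 0.605 with an estimated correlation, and 0.0699 without male replicate 2). Autism and intellectual disability genes (0 of 28 past either threshold) gave adjusted p = 0.0277, but adjusted p = 0.821 with an estimated correlation, and lost the call without males 2 or 3 or female 3 (up to 0.706). X genes reported to escape inactivation were higher (1 of 13 over all genes, 4 adjusted over the list alone; adjusted p = 0.00867 with an estimated correlation).

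In DBA/2J, the 1 autosomal gene named was Edn3, which encodes a vasoactive peptide, with 8.31 CPM in females and 4.51 in males (log2 0.85 ± 0.16, n = 3 per sex). Eif2s3x (0.63 ± 0.09) and Kdm6a (0.55 ± 0.11) were higher as in the average. In edgeR's test 10 genes passed, 6 higher and 4 lower in females, with adjusted p = 0.026 for Edn3 and Kdm6a. By limma on FPKM plus 0.1 the split was 1 higher and 3 lower. With the correction for GC content and length it was 28 higher and 13 lower, against 9 and 4 before it over the same tested genes. Edn3 (adjusted p up to 0.259) and Kdm6a (up to 0.418) lost their calls without any 1 of the 6 libraries except male replicate 3, without which 33 genes passed. For Edn3 the difference between strains was not past edgeR's threshold (interaction adjusted p = 0.084). Choroid plexus markers had a median log2 of 2.41, with 0 of 22 past edgeR's threshold over all genes and 20 higher when adjusted over the list alone (camera adjusted p = 1.4e-21, but adjusted p = 0.216 with an estimated correlation). Lbp had log2 2.15 ± 0.57 and Kl 2.03 ± 0.65. The list's mean log2 CPM was 4.41 to 5.29 in the females and 0.41 to 3.63 in the males. With that score as a covariate, chosen after the result was seen, 3 genes were higher and 4 lower, and Edn3 had log2 0.77 with adjusted p = 0.377 by edgeR. Ependymal and ciliated markers had a median log2 of 0.83, with 0 of 13 past the threshold over all genes and 1 higher over the list alone (camera adjusted p = 2.17e-05, but adjusted p = 0.592 with an estimated correlation). Meningeal fibroblast markers had 0.11, with 0 of 16 and 3 higher over the list alone (adjusted p = 0.00461, but adjusted p = 0.83 with an estimated correlation, and 0.753 without male replicate 2). Camera also called glutamate receptors, epilepsy genes and autism and intellectual disability genes lower, with 0 members past either threshold and adjusted p = 0.63 to 0.839 with an estimated correlation. Each of these calls was lost without 2 or 3 of males 2 and 3 and females 1 and 2 (up to 0.291). X genes reported to escape inactivation were higher (2 of 13 over all genes, 8 adjusted over the list alone; adjusted p = 0.000129 with an estimated correlation).

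In PWD/Ph, females had more Adora2a, the adenosine receptor of striatal neurons (2.88 against 0.54 CPM, log2 2.35 ± 0.41, n = 3 per sex), and more of the imprinted genes Magel2 (4.27 against 1.54 CPM, 1.498 ± 0.311) and Dlk1 (15.8 against 5.50 CPM, 1.48 ± 0.32). Tppp3, a tubulin-binding protein, stood at 11.7 against 5.29 CPM (1.13 ± 0.21), Synpo2 at 8.24 against 4.27 (0.94 ± 0.20), and Col23a1 (1.21 ± 0.23) and Cdc42ep1 (0.85 ± 0.17) were also higher. Lurap1l was lower in females (-0.56 ± 0.11). By edgeR 24 genes passed, 18 higher and 6 lower in females, 16 of them autosomal. edgeR's adjusted p was 0.00532 for Adora2a and 0.0425 for Magel2. With the correction for GC content and length 15 genes were higher and 10 lower in females, and by limma on FPKM plus 0.1 the split was 1 and 5. The calls of Adora2a (up to 0.213) and Col23a1 (up to 0.252) ended without male replicate 3 or female replicate 1, and that of Synpo2 (up to 0.444) without males 1 and 3 or female 3. The calls of Magel2, Dlk1, Tppp3, Cdc42ep1 and Lurap1l (up to 0.283) ended without any 1 of males 1 and 3 and females 1 and 3. The count was 12, 9, 12 and 10 without males 1 and 3 and females 1 and 3, but 1709 without male 2 and 1524 without female 2. The difference between strains was not past edgeR's threshold for Magel2 (interaction adjusted p = 0.0733), Dlk1 (0.158) or Synpo2 (0.0653).

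Of 13 thalamus and habenula markers 1 was higher in PWD/Ph females over all genes, Synpo2, and 4 when adjusted over the list alone, with a median log2 of 0.35 (camera adjusted p = 0.000767, but adjusted p = 0.134 with an estimated correlation; fry adjusted p = 0.00821). Tcf7l2, a transcription factor of the thalamus, had log2 0.75 ± 0.17. Of 12 striatum markers 1 was higher over all genes, Adora2a, and 4 over the list alone (camera adjusted p = 0.000335, but adjusted p = 0.23 with an estimated correlation; fry adjusted p = 0.0285). The camera call was lost without female replicate 1 (0.158). Penk, which encodes enkephalins, had log2 0.69 ± 0.17. With the thalamus and habenula score as a covariate, chosen after the result was seen, 9 genes passed. Dentate granule markers had a median log2 of -0.27 (0 of 17 over all genes, 1 higher and 5 lower over the list alone; adjusted p = 0.0127, but adjusted p = 0.626 with an estimated correlation, and up to 0.164 without male 2 or female 2). Meningeal fibroblast markers (median 0.60, 0 of 16 past either threshold) gave adjusted p = 0.000767, but adjusted p = 0.722 with an estimated correlation. Oligodendrocyte precursor markers (0 of 9 over all genes, 4 higher over the list alone) gave 0.00848, but adjusted p = 0.271 with an estimated correlation.

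Cytosolic ribosomal proteins, a list that also holds S6 kinases, had a median log2 of 0.11 in A/J females and 0.10 in C57BL/6J females. It was -0.20 in 129S1/SvImJ, -0.09 in DBA/1J and -0.05 in DBA/2J. Camera's adjusted p was 0.000258, 1.87e-05, 3.22e-13, 9.08e-05 and 0.00344 in these 5 strains, but adjusted p = 0.592 or more with an estimated correlation, and the difference between strains was not tested for the list. Over all genes 2 members were higher in A/J females, Rps2 (0.56 ± 0.12) and Rps27rt (0.48 ± 0.14), whose reads a near-identical copy could share, and 1 was lower, the kinase gene Rps6kb2 (-0.81 ± 0.15). When adjusted over the list alone 1 was higher and 1 lower there, and in the other 4 strains 0 of 98 passed either threshold. The call in DBA/1J was lost without female 3 (0.73), and that in DBA/2J without male 1 or female 3 (up to 0.478).

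The interaction test asked whether the difference between the sexes itself differed between strains. It did so most clearly for Dcaf1, which was higher in males of A/J and C57BL/6J and had log2 between -0.14 and 0.11 in the other 4 strains. Its level there was 45.4 to 65.9 CPM against 236 to 571 in A/J and C57BL/6J. Trank1 and Abcc5 were likewise higher in males of A/J and C57BL/6J, with Abcc5 at 155 against 107 CPM in C57BL/6J (-0.53 ± 0.08), and Trank1 at 305 against 210 (-0.54 ± 0.09). Ide had its difference in C57BL/6J, with log2 between -0.12 and 0.13 in the other strains. Zfp512b (-0.49 ± 0.07), Rreb1, Snapc4 and Fndc1 (-0.86 ± 0.15) were higher in males of A/J, and the centrosomal gene Sfi1 was higher in males of both A/J (-0.70 ± 0.14) and C57BL/6J (-0.70 ± 0.15) but at 181 CPM in females and 135 in males of DBA/2J. Uty, on the Y chromosome, had log2 from -3.09 in DBA/1J to -6.10 in DBA/2J. Its levels in the males ran from 11.7 to 16.3 CPM and from 18.2 to 21.2 there, and reads counted in females, which lack a Y chromosome, gave 1.65 ± 0.13 and 0.38 ± 0.23, so the spread in log2 lay mainly in the females.

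In edgeR's interaction test 323 genes passed, 298 of them autosomal. The adjusted p by edgeR was 2.53e-05 for Dcaf1, 0.000313 for Trank1, 0.00177 for Abcc5, Zfp512b and Uty, 0.00211 for Ide, 0.00247 for Sfi1, 0.00314 for Rreb1 and 0.00345 for Fndc1 and Snapc4. The 10 named genes kept their calls without any single library. The count rested on A/J, since 5 genes passed without that strain, Dcaf1 and Ide among those that kept their calls. Without single libraries it was 188, 850, 740, 155 and 192 (129S1/SvImJ males 1 and 2, females 1, 2 and 3), and 100, 178, 80, 209 and 151 (A/J males 1 and 3, females 1, 2 and 3). It was under 209 without C57BL/6J male 2, and 177 and 169 without females 1 and 2 of that strain. It was 500 (DBA/1J male 2), 213 (DBA/2J female 2), and 1330 and 1108 (PWD/Ph male 2 and female 2).

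The strains differed at far more genes than the sexes. In each strain comparison, 6 libraries of the strain were set against the 30 of the others, and the genes named for the size of their difference had no overlap between the strain's libraries and the others. List members were not held to this. PWD/Ph mice were housed singly and the others in groups, so strain and housing cannot be told apart for PWD/Ph. C57BL/6J mice were 63 (males) and 64 (females) days old, against 62 in other males and 62 or 63 in other females. Age therefore cannot be told apart from strain there. Sequence that differs from the GRCm38 build could lower a strain's counts without lower RNA, which was not tested. The counts of genes below stayed within 1.5 times of their values without any single library.

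In 129S1/SvImJ the higher genes included Gdpd3, a lysophospholipase D (6.32 CPM ± 1.41, SD, n = 6, against 0.27 ± 0.15, n = 30; log2 4.67 ± 0.16, SE), Fxyd2, a regulator of the sodium pump (8.49 ± 0.99 against 0.86 ± 0.57; 3.50 ± 0.12), and Lefty1, a signalling inhibitor of left-right patterning (12.5 ± 0.61 against 3.30 ± 2.56; 3.19 ± 0.08; chromosome 1, 180935022 to 180938400). The pseudogenes Rpl34-ps2 and Gm10154 were higher, and multi-copy genes such as Gm10722 and Gm10715 and the small nuclear RNA Gm22450 lower, all uncertain. The edgeR test passed 13272 genes, 6949 higher and 6323 lower, of which 4687 differed by over 1.5-fold (adjusted p = 3.65e-21 for Gdpd3). Cytosolic ribosomal proteins were higher, 86 of 98 against 5 lower over all genes and over the list alone (median log2 0.51, and 0.32 after the correction for GC content and length; adjusted p = 4.18e-17, but adjusted p = 0.993 with an estimated correlation), with Rps18 at 1.36 ± 0.06. Autism and intellectual disability genes were lower, 20 against 4 of 28 (adjusted p = 0.00659, but adjusted p = 0.993 with an estimated correlation), such as Ube3a (-1.11 ± 0.08) and Fmr1 (-0.71 ± 0.06). Their median of -0.24 was -0.01 after that correction. Mitochondrially encoded genes had a median of -0.38, 25 lower and 3 higher of 37 (adjusted p = 0.0229, but adjusted p = 0.993 with an estimated correlation and 0.0566 without female replicate 2 of the strain), and their sign flipped to 0.36 after the correction.

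In A/J, Baiap2l1, an adaptor of the actin cytoskeleton, stood at 26.5 CPM ± 2.71 against 1.86 ± 1.11 (log2 3.88 ± 0.16), and H2-T10, annotated as a polymorphic MHC class I pseudogene, at 20.9 ± 1.30 against 2.91 ± 0.66 (2.86 ± 0.06), beside the overlapping antisense gene BC023719, which the counts may not separate. Lefty1 was almost undetected, at 0.06 CPM ± 0.02 or 1 to 2 counts per library, against 5.78 ± 3.93. Fam205a3 had 0 counts in all 6 libraries, at least 85.7-fold lower than in the others, and Fam205a2 was lower by a ratio of 254.3 (95% counting interval 45.5 to 10053.9), both uncertain as copies of 1 family. In edgeR's test 6549 genes passed, 3718 higher and 2831 lower, of which 2077 differed by over 1.5-fold (adjusted p = 6.6e-19 for Baiap2l1). Microglia markers were higher, 12 of 18 against 3 lower over all genes and over the list alone (median log2 0.27; adjusted p = 0.00589, but adjusted p = 0.993 with an estimated correlation). Csf1r, the receptor that maintains microglia (0.47 ± 0.05), and Trem2 (0.66 ± 0.09) were among them. Immediate early genes were lower, 13 of 22 over all genes and over the list alone (median -0.28; adjusted p = 0.00707, but adjusted p = 0.993 with an estimated correlation). Egr1 (-0.47 ± 0.09) and Fosl2 (-0.38 ± 0.05) were among them.

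In C57BL/6J, Pttg1, the securin of mitosis, stood at 15.3 CPM ± 1.02 against 0.48 ± 0.42 (log2 5.27 ± 0.14; chromosome 11, 43420250 to 43426251), and Myoc, which encodes myocilin, at 18.1 ± 2.16 against 1.10 ± 0.80 (5.13 ± 0.17). Bspry (0.50 ± 0.14 against 2.81 ± 0.83; -2.44 ± 0.16) and Angptl7 (0.30 ± 0.19 against 1.30 ± 0.34; -2.07 ± 0.23) were lower, as were the uncertain Gm5678, Gm14165 and Gm16025. By edgeR 6835 genes passed, 4149 higher and 2686 lower, of which 2250 differed by over 1.5-fold (adjusted p = 3.75e-24 for Pttg1). With the correction for GC content and length 44.4% of 7748 calls were higher, against 60.8% of 6645 before it over the same tested genes. Oligodendrocyte and myelin markers were higher, 18 of 19 over all genes and 19 over the list alone (median log2 0.49; adjusted p = 2.1e-06, but adjusted p = 0.993 with an estimated correlation). Mal (0.65 ± 0.08) and Mobp (0.58 ± 0.09) were among them. Microglia markers were higher, 10 against 1 of 18 over all genes and 12 against 1 over the list alone (adjusted p = 0.000972, but adjusted p = 0.993 with an estimated correlation), led by Fcrls (2.104 ± 0.082) and C1qb (0.70 ± 0.07). Choroid plexus markers were higher, 15 of 22 over all genes and 16 over the list alone (median 1.23; adjusted p = 0.0168, but adjusted p = 0.993 with an estimated correlation and 0.059 without C57BL/6J male replicate 1), among them the channel subunit Kcne2 (2.00 ± 0.47). Mitochondrially encoded genes were higher, 17 of 37 and 20 over the list alone (adjusted p = 0.0184, but adjusted p = 0.993 with an estimated correlation and 0.0545 without female replicate 1), but their median of 0.26 flipped sign to -0.04 after the correction.

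In DBA/1J, S100b, a calcium-binding protein of astrocytes (ENSMUSG00000033208, chromosome 10, 76253853 to 76261159), had 0 or 1 counts per library and 2 in all, against 85.0 CPM ± 33.4 in the other strains, lower by a ratio of 5812.6 (95% counting interval 1609.0 to 47997.7). Tfpi, an inhibitor of coagulation (0.87 ± 0.32 against 5.35 ± 4.05 CPM; log2 -2.32 ± 0.18), Dnajc28 (3.57 ± 0.30 against 12.1 ± 2.57; -1.74 ± 0.09) and 2610021A01Rik (11.3 ± 1.40 against 27.2 ± 17.3; -1.08 ± 0.07) were also lower. Cd300lg, a receptor of capillary endothelium, was higher (6.11 ± 1.90 against 1.13 ± 1.07; 2.90 ± 0.15), as were small nucleolar RNAs such as Snord49a (3.21 ± 0.20), whose copies are uncertain. The edgeR test passed 10530 genes, 5616 higher and 4914 lower, of which 2381 differed by over 1.5-fold (adjusted p = 3.73e-31 for S100b). With the correction for GC content and length the majority turned, with 3454 higher and 4426 lower, against 5476 and 4832 before it over the same tested genes. Interferon and MHC class I genes were higher, 17 of 22 against 1 lower over all genes and over the list alone (median log2 0.54; adjusted p = 0.00515, but adjusted p = 0.993 with an estimated correlation). Ifit3 (1.69 ± 0.16) was among them, as was H2-D1 (1.44 ± 0.07), which is uncertain as a member of a multi-copy family whose copies could share reads. GABA receptors were lower, 9 against 2 of 17 over all genes and 10 against 3 over the list alone (adjusted p = 0.00938, but adjusted p = 0.993 with an estimated correlation), such as Gabrg1 (-0.77 ± 0.07) and Gabra4 (-0.47 ± 0.06). The median of -0.32 was -0.13 after the correction for GC content and length. Of 15 astrocyte markers 4 were higher and 4 lower over all genes and over the list alone (adjusted p = 2.01e-05, but adjusted p = 0.594 with an estimated correlation), with S100b and the glutamate transporter Slc1a3 (-0.36 ± 0.05) lower. Mitochondrially encoded genes were lower, 23 against 3 of 37 over all genes and over the list alone (median -0.38; adjusted p = 7.14e-06, but adjusted p = 0.993 with an estimated correlation).

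In DBA/2J, Gpnmb, a glycoprotein of pigment cells and microglia, stood at 0.25 CPM ± 0.20, or 1 to 4 counts per library, against 2.45 ± 0.97 (log2 -3.57 ± 0.34; chromosome 6, 49036546 to 49070929). BC035947 was higher (3.37 ± 0.25 against 0.80 ± 0.28; 2.12 ± 0.13), and the other genes named by the rule were pseudogenes, antisense or unplaced genes and so uncertain. Gm14038 and Gm45351 (higher) and Gm11824 and A830036E02Rik (lower) were among them. In edgeR's test 9756 genes passed, 4942 higher and 4814 lower, of which 2700 differed by over 1.5-fold (adjusted p = 6.43e-10 for Gpnmb). Cytosolic ribosomal proteins were lower, 71 against 4 of 98 over all genes and 72 against 4 over the list alone (adjusted p = 4.18e-17, but adjusted p = 0.993 with an estimated correlation), such as Rpsa (-0.96 ± 0.06). The median log2 of -0.34 was -0.12 after the correction for GC content and length. Mitochondrially encoded genes were higher, 17 against 1 of 37 and 19 against 2 over the list alone (median 0.33; adjusted p = 0.0101, but adjusted p = 0.993 with an estimated correlation). Erythrocyte genes were lower, 4 of 6 over all genes and 5 over the list alone (adjusted p = 0.0427, but adjusted p = 0.993 with an estimated correlation, and up to 0.0565 without DBA/2J male 2, PWD/Ph male 3 or PWD/Ph female 2). Hbb-bt (-1.46 ± 0.22) was among them, uncertain as a copy of a multi-copy family.

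PWD/Ph, a strain derived from wild mice, was the only strain housed singly, so its differences cannot be told apart from housing. Lpcat2b, a paralogue of a lipid-remodelling acyltransferase, stood at 8.57 CPM ± 1.16 in PWD/Ph against 0.02 ± 0.04 (log2 8.65 ± 0.24). Gm1976 had 0 counts in all 6 libraries, at least 109.1-fold lower than the others, and Ifit1bl1, of the interferon-induced Ifit family, was lower by a ratio of 147.5 (95% counting interval 40.8 to 1218.8). D330050G23Rik was lower by 96.2 (26.6 to 795.6), and pseudogenes such as Gm3272 and Gm14648 (higher) and Gm13394 (lower) are uncertain. Whether reads of the lower genes failed to align to the GRCm38 build was not tested, so these ratios describe counts. By edgeR 13882 genes passed, 6780 higher and 7102 lower, of which 5895 differed by over 1.5-fold (adjusted p = 5.71e-21 for Lpcat2b). With the correction for GC content and length the balance turned to 6873 higher and 5185 lower, against 6605 and 6930 before it over the same tested genes. GABA receptors were higher, 13 against 1 of 17 over all genes and over the list alone (median log2 0.40, and 0.20 after the correction for GC content and length; adjusted p = 0.0219, but adjusted p = 0.993 with an estimated correlation). Gabrg1 (1.16 ± 0.06) and Gabra2 (1.02 ± 0.06) were among them, while Gabrd was lower (-0.94 ± 0.09). Oligodendrocyte and myelin markers were lower, 14 against 1 of 19 and 15 against 1 over the list alone (median -0.62; adjusted p = 0.0155, but adjusted p = 0.993 with an estimated correlation). Mbp (-0.90 ± 0.09) and Mag (-1.01 ± 0.11) were among them. Microglia markers were lower, 13 against 1 of 18 over all genes and over the list alone (median -0.42; adjusted p = 0.00938, but adjusted p = 0.993 with an estimated correlation). Trem2 (-1.09 ± 0.11) and C1qb (-0.96 ± 0.08) were among them. Interferon and MHC class I genes were lower, 15 against 3 of 22 over all genes and over the list alone (median -1.26; adjusted p = 0.0336, but adjusted p = 0.993 with an estimated correlation and 0.0533 without PWD/Ph male replicate 2). Ifi27 (-2.32 ± 0.10) was among them, as was H2-K1 (-1.35 ± 0.14), which is uncertain as a member of a multi-copy family. Cytosolic ribosomal proteins were lower, 64 against 13 of 98 over all genes and over the list alone (adjusted p = 0.000352, but adjusted p = 0.993 with an estimated correlation), with a median of -0.30 that was -0.11 after the correction.

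DBA/1J and DBA/2J, related strains, differed at 10822 of the 19702 tested genes. S100b stood at 59.2 CPM ± 4.83 in DBA/2J (n = 6) against 2 counts in all in DBA/1J, a ratio of 4131.5 (95% counting interval 1143.1 to 34125.5). Small nucleolar RNAs were lower in DBA/2J, with Snord49a at 1.52 against 53.3 CPM and Snord55 at 2.91 against 100.9, their copies being uncertain, and the pseudogene Itpa-ps1 stood at 0.23 ± 0.18 against 7.33 ± 1.04. Snord116l9 had 0 counts in DBA/2J against 17 in all in DBA/1J, at least 3.2-fold lower. The edgeR test passed 10822 genes, 5013 higher and 5809 lower in DBA/2J, of which 3763 differed by over 1.5-fold (adjusted p = 1.13e-29 for S100b). With the correction for GC content and length 6838 passed, 3899 higher and 2939 lower, against 4905 and 5660 before it over the same tested genes. Cytosolic ribosomal proteins were lower in DBA/2J, 72 against 5 of 98 over all genes and over the list alone (median log2 -0.37, and -0.11 after the correction; adjusted p = 1.15e-09, but adjusted p = 0.993 with an estimated correlation). Rps28 (-1.25 ± 0.12) was among them. Mitochondrially encoded genes were higher, 24 against 2 of 37 over all genes and over the list alone (median 0.57; adjusted p = 1.17e-06, but adjusted p = 0.993 with an estimated correlation), such as mt-Nd3 (1.47 ± 0.15). GABA receptors were higher, 10 of 17 over all genes and over the list alone (median 0.35, and 0.09 after the correction; adjusted p = 0.0061, but adjusted p = 0.993 with an estimated correlation). Microglia markers were lower, 11 against 2 of 18 and 11 against 3 over the list alone (median -0.27, and -0.11 after the correction; adjusted p = 0.044, but adjusted p = 0.993 with an estimated correlation and up to 0.0565 without DBA/1J female 1 or DBA/2J male 2). C1qb (-1.41 ± 0.10) and Aif1 (-1.38 ± 0.13) were among them.

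**Figure D4:**
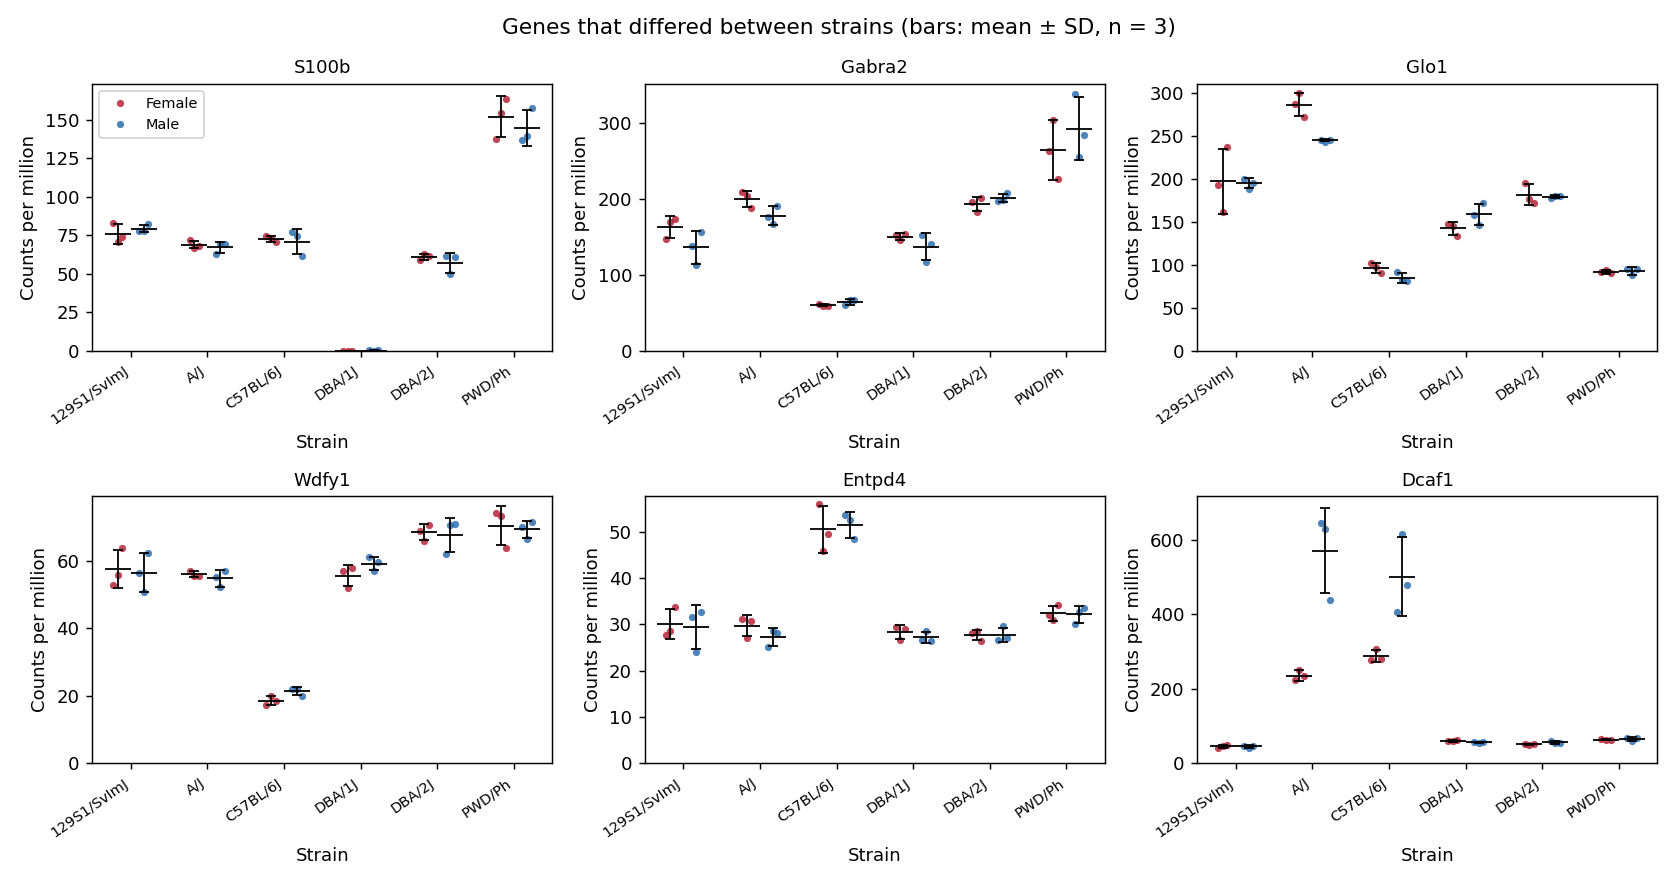
CPM (y axis) of S100b, Gabra2, Glo1, Wdfy1, Entpd4 and Dcaf1 in each library by strain and sex, with points for libraries and bars for mean ± SD (n = 3). S100b was at 0.01 CPM in DBA/1J, Gabra2 and Wdfy1 were lowest in C57BL/6J at 61.9 and 19.9 CPM over both sexes, and Entpd4 was highest there at 51.0 CPM.

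Genes with strain variants known to alter their RNA showed large differences between strains. Gabra2, a GABA receptor subunit, stood at 61.9 CPM ± 3.52 (SD, n = 6) in C57BL/6J against 143 ± 13.8 in DBA/1J to 278 ± 39.4 in PWD/Ph. Wdfy1 stood at 19.9 ± 1.90 in C57BL/6J against 55.4 ± 1.78 in A/J to 69.9 ± 3.98 in PWD/Ph. Entpd4 was higher in C57BL/6J, at 51.0 ± 3.71 against 27.7 ± 1.25 in DBA/2J to 32.3 ± 1.58 in PWD/Ph. Glo1, which detoxifies methylglyoxal, ran from 90.5 ± 8.15 in C57BL/6J and 92.1 ± 3.10 in PWD/Ph to 265 ± 24.3 in A/J. Alad, an enzyme of haem synthesis, ran from 4.83 ± 0.80 in PWD/Ph and 6.91 ± 0.79 in C57BL/6J to 24.8 ± 3.28 in DBA/1J. Nnt ran from 16.9 ± 1.70 in C57BL/6J to 29.4 ± 2.00 in PWD/Ph. Gpnmb was lowest in DBA/2J, as above. Disc1 ran from 1.41 ± 0.53 in 129S1/SvImJ to 2.36 ± 0.36 in DBA/1J, and Tyrp1 from 0.14 ± 0.08 in C57BL/6J to 0.56 ± 0.16 in A/J. In C57BL/6J against the other strains, edgeR gave log2 -1.58 ± 0.07 for Gabra2 (adjusted p = 2.05e-18), -1.62 ± 0.05 for Wdfy1 (1.03e-21) and 0.81 ± 0.05 for Entpd4 (2.12e-14). Of the 11 listed genes 10 were tested. In C57BL/6J 6 were lower and 3 higher (camera adjusted p = 6.59e-09, and adjusted p = 0.000138 with an estimated correlation), and in A/J 7 were higher and 1 lower (0.000352, and adjusted p = 0.016 with an estimated correlation), counted over all genes and over the list alone. The list was drawn up from genes already known to differ in RNA between strains. A strain difference of the list was therefore likely beforehand, and these tests are no independent result.

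**Figure D5:**
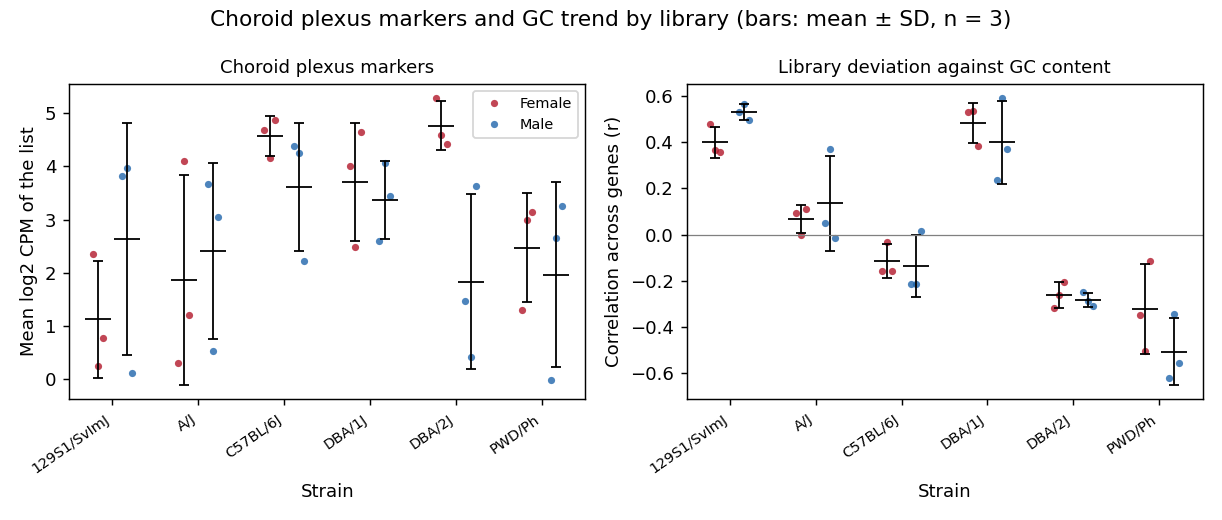
Mean log2 CPM of the choroid plexus markers in each library (left panel), and the correlation across genes of each library's deviation with GC content (right panel), by strain and sex, with bars for mean ± SD (n = 3). Choroid plexus values ran from 0.41 to 3.63 in DBA/2J males and 4.41 to 5.29 in females, and the correlation with GC content from 0.36 to 0.57 in 129S1/SvImJ and -0.62 to -0.11 in PWD/Ph.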

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

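The tests of GC content and transcript length, of thinned counts, of marker scores as covariates, of shared signs and of clustering along chromosomes were chosen only after the results were seen, while the refits with other splits of the libraries had been planned. The PWD/Ph tests were chosen once the split described here had been seen to follow the libraries' GC trend and depth.

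In 3 cases a library lay far from the other 5 of its strain. The total count of 129S1/SvImJ male replicate 2 was 18.70 M (gap 0.633 of the range), that of PWD/Ph male replicate 3 was 35.23 M (0.671), and the choroid plexus score of C57BL/6J male replicate 3 was 2.23 mean log2 CPM (0.724), each past Dixon's 95% critical value for 6 libraries. Of 12 groups tested, chance marks about 1 in 20.

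The sex effect differed between strains for 323 genes by edgeR's interaction test. Interaction adjusted p values by edgeR were 2.53e-05 for Dcaf1, 0.000313 for Trank1, 0.00177 for Abcc5, Uty and Zfp512b, 0.00211 for Ide, 0.00247 for Sfi1, 0.00314 for Rreb1, and 0.00345 for Fndc1 and Snapc4. Among genes named within 129S1/SvImJ they were 0.00544 for Mmp14, 0.00665 for Ier5, 0.0178 for Atr, 0.0274 for Dpyd and 0.0296 for Cldn5. Those of DBA/1J were 0.0197 for Cyp51, 0.0262 for Hsp90b1 and 0.0322 for Calr, and those of PWD/Ph 0.0151 for Lurap1l, 0.0235 for Adora2a, 0.0262 for Col23a1, 0.0286 for Cdc42ep1 and 0.0369 for Tppp3. For A/J and C57BL/6J they were 0.0265 for Gm16244, 0.0303 for ENSMUSG00000095552, 0.036 for Gm10045, 0.0369 for Muc3a, 0.0393 for BC030499, 0.0403 for Dbp, 0.0436 for Slc13a1 and 0.0437 for Dnah5, and Xist had 0.0369. Chance cannot be excluded for the interaction count, since 5 of the 40 splits, the real one included, gave as many genes and the highest other gave 4154. A split that calls several times the real count points to a structure of the samples.

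More genes differed between the sexes in A/J (1049) than in the other strains. The fit without the GC and length trend called 1562 genes, against 995 over the same tested genes with it, and 904 of the 1562 were among the 1049. Thinned A/J libraries gave 1006 calls and the choroid plexus score as a covariate 954, which argues against each as the whole cause. An effect of sex that the other strains share in a weaker form may contribute. Of the 937 autosomal calls, 69.6% had the same sign in the average of the other 5 strains. But 218 of 1000 combinations of other splits reached as high a share (highest 91.7%), so such a shared effect stays open. Over 18307 autosomal genes, the A/J sex effect had a correlation of 0.46 with C57BL/6J, 0.16 with PWD/Ph and 0.08 with DBA/2J. The correlation was -0.09 with 129S1/SvImJ and -0.16 with DBA/1J. The shared sign may therefore rest mainly on C57BL/6J, which was not tested. For A/J the 10 splits are too few for a share under 0.05, and the highest other called 0 genes, while the females' age, 1 day above the males', cannot be told apart from sex and stays open.

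DBA/1J and DBA/2J differed at 10822 genes. The fit without the GC and length trend called 6838 genes, of which 5084 were among the 10822, against 10565 with the trend over the same tested genes, and thinned counts gave 9415. This argues against either as the whole cause, though the trend may account for part. Inherited sequence differences acting on nearby genes stay open: over 252 windows of 10 Mb, genes differing by over 2-fold varied 1.29 times as much as the median shuffle (52 of 1000 shuffles as high). Genes differing by under 1.5-fold varied 1.57 times as much (0 of 1000), but 1.18 times (73 of 1000) once the trend was removed. The reading of this test was made more cautious after its values were seen, because windows differ in GC content and because differences spread evenly over the genome form no clusters, so that a lack of clusters excludes nothing.

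A split of the PWD/Ph libraries across the sexes, with male replicates 1 and 3 and female replicate 2 against the others, called 3557 genes, against 24 for sex, which points to a structure of these samples. The fit without the GC and length trend called 997 genes, against 3562 with it over the same tested genes, so that this trend may account for part of the split. Thinned counts gave 3452 and the thalamus and habenula score as a covariate 2373, which argues against depth and against such tissue as the whole cause. No biological explanation was tested, since the design names no such group.

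For the averaged sex effect (47 genes) 1 of 40 splits, the real one, gave as many, and the highest other gave 45. This excludes chance only with the sex-linked calls counted, and not for the 29 autosomal calls, which are fewer than 45. The real count was 38 with DESeq2's size factors, 42 with a filter of 1 CPM and down to 18 without single libraries, where other splits were not refitted. Of the 47, 10 are X-linked and 4 Y-linked. For each strain against the others and for the DBA pair, the real count was the highest of 40 splits. The real and highest other counts were 13272 and 5820 (129S1/SvImJ), 6549 and 5049 (A/J), 6835 and 28 (C57BL/6J) and 10530 and 12 (DBA/1J). They were 9756 and 3163 (DBA/2J), 13882 and 871 (PWD/Ph) and 10822 and 7365 (DBA pair). This excludes only that strain labels bear no relation to the counts. The other splits mixed strains, which adds strain differences to the estimated spread and can lower their counts. Nor can they separate strain from what its libraries share, such as the GC trend, housing or possibly lane. For sex within the remaining strains the 10 splits are too few for a share under 0.05. Chance is not excluded for any of them, and in 129S1/SvImJ and PWD/Ph other splits called more genes than sex did. The real count and the highest other were 20 and 527 in 129S1/SvImJ (4 splits as large, the real one included), 55 and 0 in C57BL/6J, 12 and 1 in DBA/1J, 10 and 1 in DBA/2J, and 24 and 3557 in PWD/Ph (3 splits as large, the real one included). The 129S1/SvImJ split with 527 genes also points to a structure of the samples.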

How the results depend on the processing

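The GC and length correction, the marker score covariates and the fits without doubtful libraries were tests chosen only after the results were seen. The cause was not tested for any change below, except that fits with fewer libraries or strains have fewer samples by construction.

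The averaged sex effect (47 genes) moved to 164 without the low-count filter, 204 with the GC and length correction, 175 by DESeq2, 792 without 129S1/SvImJ, 17 without A/J, 13 without C57BL/6J, 25 without DBA/2J, 214 without PWD/Ph, 24 without the 3 shallow DBA/2J libraries and 29 without the 2 C57BL/6J males rich in Gh. Without the filter the counts within strains became 64 in 129S1/SvImJ, 108 in C57BL/6J, 25 in DBA/1J, 134 in DBA/2J and 103 in PWD/Ph, and 1071 for the interaction. With the GC and length correction they became 31 in 129S1/SvImJ, 136 in C57BL/6J, 21 in DBA/1J and 41 in DBA/2J, 556 for the interaction and 6838 for the DBA pair. From each strain's own 6 libraries they were 8 in 129S1/SvImJ, 2069 in A/J, 563 in C57BL/6J, 7 in DBA/1J, 182 in DBA/2J and 6 in PWD/Ph. DESeq2 called 52 in 129S1/SvImJ, 156 in C57BL/6J, 20 in DBA/1J, 65 in DBA/2J, 265 in PWD/Ph and 1325 for the interaction. On log2 FPKM plus 0.1 and plus 1, limma called 5 and 6 in 129S1/SvImJ, 7 and 5 in C57BL/6J, 5 and 5 in DBA/1J, 4 and 6 in DBA/2J, and 6 and 5 in PWD/Ph. The choroid plexus covariate gave 115 in C57BL/6J, the thalamus and habenula covariate 9 in PWD/Ph, the fit without the 2 males rich in Gh 12 in C57BL/6J, and that without the 3 shallow libraries 6 in DBA/2J. These last fits leave 1 C57BL/6J male and 1 DBA/2J female, assumed to vary like the other groups, so a lower count follows in part from the design. The interaction gave 5 without A/J, 98 without C57BL/6J and 622 without PWD/Ph.

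With the replicate block, the averaged sex effect had 61 genes, 15 higher and 46 lower, of which 29 were among the 47. Counts that moved by over 1.5 times were 8 in 129S1/SvImJ, 7 in DBA/1J, 9 in PWD/Ph and 162 for the interaction. The numbers do not pair samples by design, and 5 of 18 male libraries correlated best with the female of their own number among the 3 of their strain. Over all strains this is no hint of pairing. In 129S1/SvImJ 2 of 3 did so (correlations 0.197 and 0.362, and -0.079 for replicate 1), too few to judge.

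Leaving out each library gave 18 to 167 genes for the averaged sex effect, 8 to 368 in 129S1/SvImJ, 204 to 788 in A/J, 16 to 90 in C57BL/6J, 7 to 69 in DBA/1J, 7 to 33 in DBA/2J, 9 to 1709 in PWD/Ph and 80 to 1330 for the interaction. The strain comparisons and the DBA pair stayed within 1.5 times of their counts. Gene lists called by camera went from 7 to 3 with an estimated correlation and 4 by fry for the averaged sex effect, from 53 to 16 and 24 within strains, and from 32 to 2 and 111 between strains. For named genes, leaving out libraries kept 3519 results past the threshold and ended 297, other settings kept 1542 and ended 252, and none reversed. These genes had been chosen by their clear differences in the same libraries, so the lack of reversals follows largely from that choice. Genes that a setting filtered out or left without an adjusted p were not counted. Leaving out libraries ended none for the strain comparisons and the interaction, so all 297 fell on sex effects. Kept and ended were 675 and 117 averaged over strains, 44 and 34 in 129S1/SvImJ, 58 and 38 in A/J and 42 and 54 in C57BL/6J. They were 19 and 17 in DBA/1J, 14 and 10 in DBA/2J and 27 and 27 in PWD/Ph. Depth limits the low levels most in DBA/2J, with 6493512 counts in female replicate 3.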

Other observations

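The values here were looked at after the results were seen, and no test of an explanation was run on them. Across 18307 autosomal genes, which are not independent replicates, the sex effects of A/J and C57BL/6J had a correlation of 0.46 (0.45 with the GC and length correction), against -0.16 to 0.16 for the other 14 pairs of strains. The A/J and C57BL/6J effects share no libraries.

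Gfap, chosen after its values were seen, had 444 CPM ± 408 (SD, n = 6) in DBA/1J, with 4945 to 28613 counts per library. It stood at 612 CPM ± 576 in DBA/1J males and 276 ± 16.1 in females (n = 3 each), against 196 CPM ± 11.5 in DBA/2J to 284 ± 17.2 in C57BL/6J. The females thus lay within the range of the other strains. The SD of the males was almost as large as their mean, so a single male library could carry the difference. The choroid plexus markers had a median pairwise correlation of 0.94 over the libraries.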
